A study of Tursiops truncatus with 28 samples.

How the data were processed

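Total RNA of skin was extracted with a lipid tissue column kit with DNase digestion, and directional libraries were prepared for Illumina sequencing, per the labels' protocols. The submitters' processing notes name FastQC 0.1, Trimmomatic 0.33, TopHat2 2.1.1, Bowtie and Cufflinks 2.2.1, and the series' design text names the NIST Tur_tru v1 assembly as the guide genome. Settings of these tools, the gene annotation and the use of strand in counting are not given in the sources used here. The authors deposited a table with 1 column per library and 1 row per locus. Its unit is not written in the table and was taken to be FPKM as the authors' Cufflinks step makes it: the deposited values are not whole, library totals are unequal, and the value of a single fragment falls with locus length. Whether the authors applied a further scaling between libraries is not given in the sources used here.

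FPKM divides by the mapped fragments of each library, so a locus that takes a large share of a library lowers all other values there, and very short loci can reach very high values. The 808 loci under 200 bases took between 0.0123% and 16% of a library's summed FPKM. Only 23 of them passed the filter, and leaving them out was among the alternatives. Each row is named by a scaffold and an interval, counted from 0 in the table and given here with the first base as 1. The gene table at hand describes another assembly, and none of its identifiers matched, so 0 loci received a gene name. The 33 gene lists chosen before the data were examined could not be tested for that reason. The planned rule, which named the 10 largest rises and falls per comparison among genes with a symbol, was reduced to the 2 largest rises and the 2 largest falls past the threshold per comparison, given by position. The mitochondrial sequence was recognised by its sequence identifier, NC_012059.1, and its 12 loci of at least 500 bases, out of 36, were used as a group chosen after the data were examined. Of the tested loci 3507, or 26.6%, overlap another locus of the table, and fragments of such loci cannot be told apart without the strand, which the row names lack.

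Columns were matched to samples by exact title, and every column had a sample. Session came from the sampling date and sex from the sex label. The title of July 2016 female 6 carries the year 2015 while its date is in 2016. The date was used, and leaving that library out was an alternative. Every library came from a different animal, so the spread between libraries includes that between animals. No sequencing or library batch is given in the sources used here.

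Values were taken as log2(FPKM + 1), so log2 differences understate the changes of low loci. Loci with a mean of at least 1 FPKM over the 28 libraries were tested, 13192 in all. A linear model with session and sex as additive terms was fitted to all libraries with limma 3.58.1 in R 4.3.3 (24 residual degrees of freedom, empirical Bayes with trend and robust settings). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the tested loci, and a locus was called at an adjusted p under 0.05. The difference of the June to September change between the sexes was tested in a model of the 5 groups of session and sex. The mitochondrial group was tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry (adjusted p = 0.485 for sex). Calls per scaffold were tested with one-sided Fisher's exact tests over the 156 scaffolds with at least 10 tested loci. Figures were drawn with matplotlib 3.10.9.

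Depth per library is not given. Relative depth was taken from the ratios of low values between libraries, at 4754 loci with a mean under 0.5 FPKM that were above 0 in at least 5 libraries. In 100% of the 378 pairs of libraries the relative depths lay within 0.05 on the log2 scale of the ratio measured in that pair. In simulated whole fragments at 5000 loci the largest error of this estimate was 0.000395 on the log2 scale. The simulation gave each locus the same fragment weight in every library and little noise, as the estimate itself assumes. Its error therefore does not bound that in the deposited values. No count test was used, because the values are not counts.

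The model was tested on simulated data of 13192 loci, with 50 loci changed by each fold. Changes were added on the log2(FPKM + 1) scale, only at loci with a mean log2 value above that of 5 FPKM. The noise was normal and independent between loci. The 3773 tested loci with a mean of 1 to 5 FPKM were never changed, so the shares below do not cover them. The shares may also differ for another number of changed loci. Of loci changed 1.5-fold, 70% were called between September and June 2017, 76% between July 2016 and June 2017, 52% between September 2017 and July 2016 and 56% between the sexes. For 2-fold changes these shares were 96%, 94%, 86% and 92%. Between 8 and 12 unchanged loci were called per comparison, and no call had the wrong direction.

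The alternatives set before the data were examined were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 FPKM, quantile normalization, median of ratios scaling, array weights, empirical Bayes without a trend, females alone, the libraries of the compared sessions alone, the 2017 libraries alone for sex, a model of 5 groups, and leaving out each library in turn. Alternatives chosen after the data were examined were leaving out loci under 200 bases, the mitochondrial level or the log2 relative depth as a covariate, removing each library's trend with locus length, leaving out the 3 libraries with the highest share in the 10 most abundant loci, and dividing the July libraries between comparisons. Calls were also counted for 100 splits of the libraries per comparison, the real split included.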

Results

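RNA was sequenced from archived skin of 28 common bottlenose dolphins (Tursiops truncatus) sampled during health assessments in Barataria Bay, Louisiana. Each library came from a different animal. The sampling dates fall into 3 collection sessions: 9 females were sampled in July 2016, 8 females and 3 males in June 2017, and 5 females and 3 males in September 2017. No male was sampled in 2016, so the comparisons with July 2016 rest on females together with a sex effect measured in the 2017 libraries. July 2016 differs from the 2017 sessions in year as well as in month, and year and month cannot be separated for it.

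The table held 24091 loci on 359 sequences, each given as an interval of the NIST Tur_tru v1 genome with no gene name. Loci are therefore described by position, and the genes and exons they hold were not analysed here. Of these loci, 2900 were listed at 0 in every library, and between 17418 and 18259 were above 0 in a library. Summed FPKM, in which fragments are divided by transcript length and by the mapped fragments of the library, ran from 815690 to 1078077 per library. The total number of reads per library is unknown, but the steps between low values gave relative depths from 0.762 to 1.48, a 1.94-fold range. Mean relative depth was 1.04 ± 0.173 (SD, n = 9) in July 2016, 0.924 ± 0.142 (n = 11) in June 2017 and 1.11 ± 0.187 (n = 8) in September 2017. Among females the log2 relative depth did not differ between any pair of sessions past the threshold (exact permutation tests, two-sided, p between 0.168 and 0.639). The 3 June 2017 males lay at 0.777 to 0.978 and the 3 September 2017 males at 1.05 to 1.18, with no overlap. Libraries of the same group correlated with r between 0.929 and 0.959 across loci, which are not independent replicates, and no pair of columns was identical.

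The 10 most abundant loci of a library took 27.6% ± 4.44 (SD, n = 28) of its summed FPKM, from 22.2% to 41%. The most abundant locus, at positions 34011 to 36278 of scaffold NW_017844407.1, held a mean of 50200 ± 6010 FPKM (SD, n = 28) and varied 1.71-fold between libraries. The mitochondrial loci of at least 500 bases, 12 in number, took 3.09% ± 1.08 (SD, n = 28). Levels were tested at 13192 loci with a mean of at least 1 FPKM.

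The comparison of males with females also checked the sex labels. At positions 1473011 to 1504352 of scaffold NW_017842989.1, the 22 female libraries held 42.4 ± 6.48 FPKM (SD), from 32.5 to 54.9, while the 6 male libraries held 0.222 ± 0.369, with a highest value of 0.973. The log2 difference, male minus female, was -5.24 (SE 0.121, adjusted p = 3.54e-23, limma), and no library lay on the side of the other sex. In all, 12 loci differed between the sexes, 11 of them higher in females and 1 higher in males. The other 10 loci that were higher in females differed far less, between 1.38-fold and 1.75-fold. The largest of these, at positions 3169686 to 3220613 of scaffold NW_017842470.1, held 14.2 ± 1.75 FPKM in females (SD, n = 22) and 7.60 ± 1.06 in males (SD, n = 6), with a log2 difference of -0.81 (SE 0.0948, adjusted p = 1.79e-05).

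**Figure D1:**
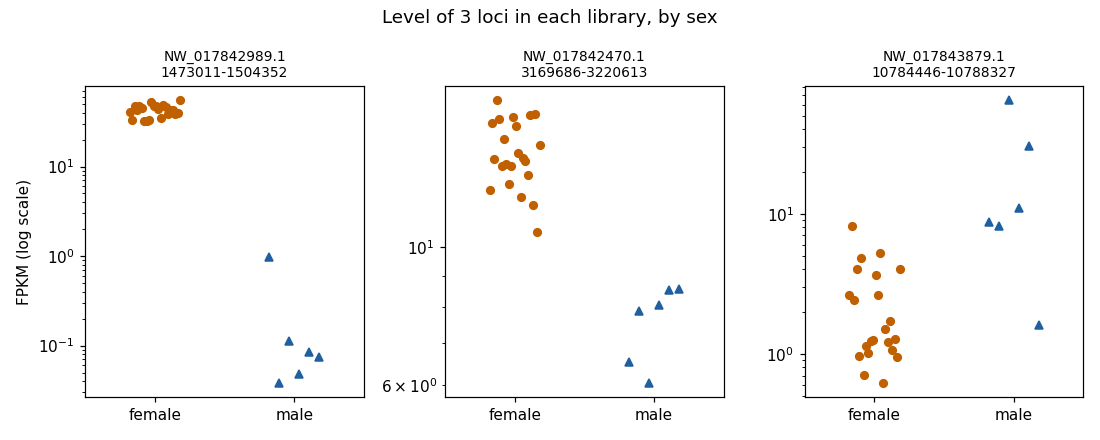
FPKM (log axis) of 3 loci in each of the 22 female and 6 male libraries, with 1 point per library and the locus position above each panel. At the left locus every female library lies at or above 32.5 and every male library at or below 0.973, at the middle locus the females also lie above all males, and at the right locus the ranges overlap.

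The loci that were higher in females sat on 5 scaffolds. Of the 97 tested loci of scaffold NW_017843730.1, 4 were called, where 0.0809 were expected from the share over all loci (one-sided Fisher's exact test, adjusted p = 0.000136 over 156 scaffolds). Scaffold NW_017842689.1 held 3 such loci among 31 tested (adjusted p = 0.000149) and scaffold NW_017842470.1 held 2 among 22 (adjusted p = 0.00752). Such tests treat loci as independent, which neighbouring loci are not. The locus that was higher in males, at positions 10784446 to 10788327 of scaffold NW_017843879.1, varied widely among them, from 1.60 to 64.4 FPKM (n = 6), against 2.37 ± 1.90 in females (SD, n = 22). Its log2 difference was 2.31 (SE 0.448, adjusted p = 0.0219). With session and sex in the model its level also rose with that of a much more abundant locus, at positions 35881716 to 35882230 of scaffold NW_017844169.1 (slope 0.461 per doubling, adjusted p = 0.00331), which held 65500 ± 69100 FPKM in males (SD, n = 6) and 13540 ± 24300 in females (SD, n = 22) and was also highest in June 2017 male 3. The abundant locus was chosen after its values were seen, and its own sex difference was not called (adjusted p = 0.445). The call of the locus at positions 10784446 to 10788327 was lost with the 2017 libraries alone (log2 difference 2.31) and without June 2017 male 3 (1.83), September 2017 male 1 (2.30) or September 2017 male 2 (2.03). It was also lost without the 3 libraries with the highest share in the 10 most abundant loci (1.77), of which June 2017 male 3 is a member. Without June 2017 male 3 the count of loci differing between the sexes was 6.

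Skin sampled in July 2016 differed from skin sampled in June 2017 at 955 loci, of which 667 were higher and 288 lower in July. Most of these differences were small: the median called locus differed 1.38-fold, and 73 loci differed by more than 2-fold, 38 of them higher and 35 lower. The largest rise was at positions 55626071 to 55633530 of scaffold NW_017844429.1, from 54.8 ± 15.4 FPKM in June 2017 (SD, n = 11) to 182.7 ± 35.6 in July 2016 (SD, n = 9). Its log2 difference was 1.77 (SE 0.169, adjusted p = 4.49e-07), and every July library, at 138.2 FPKM or more, lay above every June library, at 81.7 or less. The next largest rise, at positions 26253993 to 26254308 of scaffold NW_017844458.1, was from 26.6 ± 17.3 to 67.7 ± 28.8 FPKM (log2 difference 1.63, SE 0.364, adjusted p = 0.00725).

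Among the loci that were lower in July 2016, that at positions 7159498 to 7174906 of scaffold NW_017843244.1 held 3.71 ± 1.91 FPKM in July (SD, n = 9) and 15.9 ± 6.58 in June 2017 (SD, n = 11). Its log2 difference was -2.18 (SE 0.233, adjusted p = 2.55e-06), and the highest July library, at 6.91 FPKM, lay below the lowest June library, at 7.75. A second locus, at positions 10469066 to 10597095 of scaffold NW_017843879.1, was listed at 0 in 8 of the 9 July libraries and at 6.05 FPKM in the other, July 2016 female 4. In June 2017 it was above 0 in 11 of 11 libraries, with a lowest value of 0.886 and a median of 4.93 FPKM (log2 difference -2.27, SE 0.361, adjusted p = 0.000348). Both loci overlap another locus of the table, and the deposited values do not show how fragments were divided between overlapping loci.

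**Figure D2:**
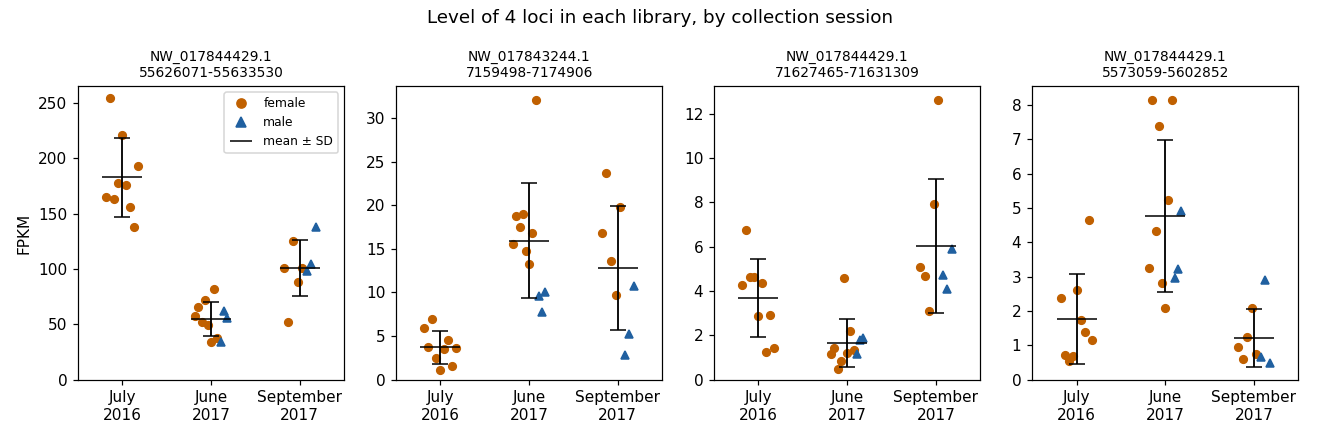
FPKM of 4 loci in each library by collection session, with 1 point per library, circles for females, triangles for males, and lines for the mean ± SD of the session (n = 9, 11 and 8). In the first 2 panels the 9 July 2016 libraries lie apart from the 11 June 2017 libraries, at 138.2 FPKM or more against 81.7 or less and at 6.91 or less against 7.75 or more. The last 2 panels show loci called between September and June 2017.

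Calls between July 2016 and June 2017 were unevenly spread along the genome. Scaffold NW_017842632.1 held 10 loci that were lower in July among 95 tested, against 2.07 expected (one-sided Fisher's exact test, adjusted p = 0.00646), and scaffold NW_017844438.1 held 7 among 60, against 1.31 expected (adjusted p = 0.0246). Scaffold NW_017844458.1 held 34 loci that were higher in July among 356 tested, against 18 expected (adjusted p = 0.0428). These tests treat loci as independent, which neighbouring and overlapping loci are not, so their p-values may be too small. Neighbouring tested loci that do not overlap each other were called in the same direction in 62 pairs, against a mean of 35.9 pairs when calls were placed at random (permutation p = 1e-04, the smallest that 10000 draws can give). With every locus that overlaps another left out, an alternative chosen after the data were examined, there were 47 such pairs against a mean of 28.7 (permutation p = 4e-04). Random placement did not take the level of the loci into account. Runs of 3 neighbouring loci called in the same direction numbered 5. Of these, 4 were higher in July, with log2 differences from 0.258 to 1.77, and 2 of the 4 held no locus that overlaps another. The run that was lower, at positions 12408066 to 12423502 of scaffold NW_017842757.1, had log2 differences from -1.94 to -1.39, and 2 of its 3 loci overlap another locus.

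Direction differed with the length of the locus, introns included. Among called loci longer than 20000 bases 80.2% were higher in July, 453 of 565, and among shorter ones 54.9%, 214 of 390 (Fisher's exact test across loci, which are not independent, p = 8.26e-17). With median of ratios scaling these shares were 64.3% and 35%, so that most calls at the shorter loci were then lower in July. On the deposited scale direction also differed with level. At a mean of 1 to 5 FPKM 105 loci were called higher and 77 lower in July, against 114 and 23 at 100 FPKM or more. Length and level were not separated. The split between higher and lower calls also changed with the scaling of the libraries: 69.8% of the called loci were higher in July on the deposited scale, 51% with median of ratios scaling and 53% with quantile normalization. Fitted without the September libraries, the count of called loci was 604.

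September 2017 differed from July 2016 at 257 loci, 86 of them higher and 171 lower in September. The share that was higher in September was 33.5% on the deposited scale, 38.7% with median of ratios scaling and 47.6% with quantile normalization. On scaffold NW_017843244.1 the locus at positions 7159498 to 7174906, which was lower in July 2016 than in June 2017, was also lower in July 2016 than in September 2017. It held 12.8 ± 7.10 FPKM in September (SD, n = 8), with a log2 difference of 1.88 (SE 0.258, adjusted p = 0.000272). September females held 16.7 ± 5.40 FPKM (SD, n = 5) and males 2.871, 5.265 and 10.72, the first 2 within the July range of 1.05 to 6.91. June 2017 females held 18.5 ± 5.85 (SD, n = 8) and males 9.13 ± 1.21 (SD, n = 3). The locus was not among those called between the sexes. A locus that fell, at positions 26205383 to 26243865 of scaffold NW_017844429.1, held 7.38 ± 3.03 FPKM in July 2016 (SD, n = 9) and 2.23 ± 1.73 in September (SD, n = 8), with a log2 difference of -1.37 (SE 0.291, adjusted p = 0.0117). Its call was lost when only the libraries of the sessions compared were fitted (log2 difference -1.35). Scaffold NW_017842814.1 held 6 loci that were lower in September among 56 tested, against 0.726 expected (one-sided Fisher's exact test across loci, which are not independent, adjusted p = 0.0129).

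The remaining named loci of this comparison lay near the floor in some libraries and overlap another locus. That at positions 62033797 to 62034400 of scaffold NW_017844429.1 was listed at 0 in 7 of the 9 July libraries, and at 0.238 and 0.114 FPKM in the others. Its September values were 2.53, 0, 3.88, 8.91 and 4.17 FPKM in the females and 0.111, 3.75 and 0.196 in the males (log2 difference 1.80, adjusted p = 0.0213). The call was lost without September 2017 female 3, 4 or 5 (log2 difference 1.72, 1.53 and 1.71). The locus at positions 9559851 to 9560265 of scaffold NW_017844293.1 was listed at 0 in all 5 September females and at 7.52, 22.4 and 0 FPKM in the September males. In July it was listed at 0 in 2 libraries and at 18.8, 18.3, 13.7, 9.64, 23.6, 12.4 and 20.2 FPKM in the others (log2 difference -3.20, adjusted p = 0.0435). That call was lost without any of July 2016 females 2 to 8, any September female, June 2017 males 1 or 2, or September 2017 male 3, with log2 differences from -3.20 to -2.98. It was also lost in 8 of 16 other alternatives: a pseudocount of 0.1 (log2 difference -5.62), no filter (-3.20), females alone and these sessions alone (-3.18 in each), without the library whose title year differs from its date (-3.02, the same fit as without July 2016 female 6), the mitochondrial level (-3.04) or relative depth (-3.08) as a covariate, and without the 3 libraries with the highest share in the 10 most abundant loci (-3.18). The count of 257 fell to 160 in females alone and to 98 in the libraries of these sessions alone, and it was 169, 160, 152 and 145 without September 2017 female 2, 3, 4 and 5.

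Both comparisons with July 2016 called 170 loci in the same direction relative to July, 120 higher and 50 lower in July 2016 than in either 2017 session, and no locus in opposite directions. Independent lists of these sizes would share 10.5. This overlap was chosen after the data were examined, whereas that of both comparisons with September 2017 was planned. The planned overlap held 0 loci in the same direction and 1 in opposite directions, with only 5 calls between September and June 2017. All libraries were also simulated without any session difference, with the July libraries used in both comparisons. These shared 0 loci, but noise alone gives few or no calls, so that count was fixed beforehand and gives no baseline. The log2 differences correlated across loci with r = 0.637, against 0.564 in the simulation, and their covariance was 0.0570 against 0.0301. For the comparisons that share September 2017, r was 0.42, against 0.553 in the simulation. The simulated noise was independent between loci, whereas 1952 of the tested loci went with the mitochondrial level. The simulation therefore gives no fair baseline for r or the covariance, and nothing is concluded from the differences. With the July libraries divided between the comparisons, so that none was used in both, the median over 20 divisions was 24.5 shared loci (19 to 39), against 0.908 for independent lists. Both comparisons still came from the same fit, with the same spread per locus. In the undivided fit 4.82% and 0.954% of loci with a mean of 1 to 5 FPKM were called in these comparisons. At 100 FPKM or more these shares were 14.9% and 8.27%. Independent lists are therefore no fair baseline for either count of shared loci.

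Within 2017, September differed from June at 5 loci, 4 of them higher and 1 lower in September. The locus at positions 71627465 to 71631309 of scaffold NW_017844429.1 rose from 1.64 ± 1.09 FPKM in June (SD, n = 11) to 6.02 ± 3.03 in September (SD, n = 8), with a log2 difference of 1.41 (SE 0.247, adjusted p = 0.0267). At positions 54976544 to 54993714 of scaffold NW_017843160.1 the level rose from 27.5 ± 6.21 to 52.2 ± 11.5 FPKM (log2 difference 0.88, SE 0.154, adjusted p = 0.0267). The locus that fell, at positions 5573059 to 5602852 of scaffold NW_017844429.1, held 4.77 ± 2.22 FPKM in June and 1.21 ± 0.855 in September (log2 difference -1.36, SE 0.253, adjusted p = 0.0344). At an unadjusted p under 0.05 there were 1580 loci, 12% of those tested. Without June 2017 female 2 or 8, September 2017 female 4 or 5, or September 2017 male 1 no locus passed, although the log2 differences of the 3 loci above moved little (1.24 to 1.43, 0.86 to 0.87 and -1.44 to -1.29). The call of the locus that fell was also lost without June 2017 female 4, June 2017 male 3 or September 2017 male 3, with log2 differences of -1.30, -1.32 and -1.30. No locus passed in females alone, where the log2 differences were 1.52 (SE 0.326), 0.73 (SE 0.185) and -1.47 (SE 0.309), or with relative depth as a covariate, where they were 1.48 (SE 0.278), 0.86 (SE 0.174) and -1.35 (SE 0.287). The standard errors were larger in both fits. With no filter on the mean level, the call of the locus that fell was lost at an unaltered log2 difference of -1.36, since more loci were tested. With median of ratios scaling 21 loci passed, 12 higher and 9 lower.

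The change from June to September 2017 was compared between males and females. No locus differed in that change (limma, smallest adjusted p = 0.749), and 487 loci, 3.69% of those tested, had an unadjusted p under 0.05. Each male group held 3 libraries.

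None of the 12 mitochondrial loci was called in any comparison, while their shared level varied from library to library. Males were lower at 12 of 12 (median log2 difference -0.368), with a camera adjusted p = 0.0044 at the preset correlation and an adjusted p = 0.73 with an estimated correlation. Their mean log2 level was 9.29 ± 0.265 in males (SD, n = 3) and 9.97 ± 0.609 in females (SD, n = 8) in June 2017, whereas in September 2017 males were not lower, at 10.1 ± 0.519 (SD, n = 3) against 10.04 ± 0.574 (SD, n = 5). Whether the difference between the sexes changed between these sessions was not tested for the group. September 2017 was higher than July 2016 at 11 of 12 (median log2 difference 0.34, camera adjusted p = 0.0444, and adjusted p = 0.73 with an estimated correlation). Their mean log2 level ran from 8.89 to 10.9 between libraries and went with the first principal component of all the other tested loci, which held 10.3% of their variance. Over the 28 libraries Pearson's r was 0.908 and Spearman's rho 0.871 (permutation p = 1e-05 for each, the smallest that 100000 draws can give), and r was 0.888 without the 2 libraries farthest from the median level. The relation held within July 2016 (r = 0.963, rho = 0.933, exact permutation p = 0.00019 and 0.00075, n = 9), June 2017 (r = 0.918, rho = 0.90, permutation p = 0.00014 and 0.00031, n = 11) and September 2017 (r = 0.961, rho = 0.905, exact permutation p = 0.00057 and 0.00456, n = 8). Within these sessions r was 0.978, 0.773 and 0.908 without the 2 farthest libraries. Across the 7 relations computed in this family the Benjamini-Hochberg adjusted p of Pearson's r for these 4 was 7e-05, 0.000402, 0.000402 and 0.000798.

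**Figure D3:**
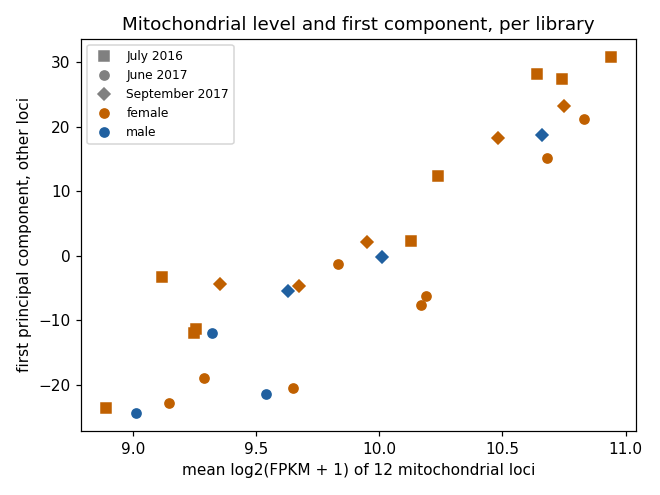
Mean log2(FPKM + 1) of the 12 mitochondrial loci (horizontal axis) and score on the first principal component of all other tested loci (vertical axis, no unit), with 1 point per library, shape for session and colour for sex. Level and score rise together in all 3 sessions (r = 0.908 over 28 libraries), but not along the same line. Several June 2017 libraries score lower than others at a similar level, such as June female 3 (-20.4 at 9.65) against September female 1 (-4.73 at 9.67). Others do not, such as June male 2 (-11.9 at 9.32) against July female 1 (-11.9 at 9.25).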

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

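The tests of the covariates for depth and mitochondrial level, of the length trend, of the collection or library batch, of the share of higher calls under another scaling and of the loci around the sex calls were chosen after the results were seen. Among the groups of 9, 8 and 5 females, 53 sets of library measures and named loci were screened for a library far from the others, and 5 stood out, where chance gives about 1 in 20. Gaps are given as shares of the range of the group on the log2 scale, with log2(FPKM + 1) for loci. June 2017 female 6 had a summed FPKM of 1078077 against 944100 or less in the other June females (gap 0.585 of the range), and its 10 most abundant loci took 36.8% against 27.8% or less (gap 0.822). In July 2016 the locus at positions 10469066 to 10597095 of scaffold NW_017843879.1 held 6.05 FPKM in female 4 and was listed at 0 in the other July libraries (gap 1). The locus at positions 7159498 to 7174906 of scaffold NW_017843244.1 held 32.1 FPKM in June 2017 female 8, against 13.3 to 19.0 in the other June females (gap 0.602). Likewise, the locus at positions 62033797 to 62034400 of scaffold NW_017844429.1 held 0.238 FPKM in July 2016 female 1, against 0.114 or less in the other July libraries (gap 0.495).

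Of the 955 loci that differed between July 2016 and June 2017, 730 were called in the same direction with relative depth as a covariate, with the length trend removed 721, with the mitochondrial level as a covariate 955, and with median of ratios scaling 722, which argues against each of these as the whole source. The excess of higher over lower loci stays open: with median of ratios scaling 51% of the calls were higher in July, but that scaling centres the ratios between libraries, which brings the calls towards balance by construction. The larger share of higher calls at long loci stays open as well: it was 29.3 percentage points with that scaling, which moves long and short loci of a library alike and so cannot test it, and 3.41 points with the length trend removed, which takes it out by construction. Chance is an unlikely source of the count, since 1 of 100 splits of the females, the real one, gave 955 loci or more and the highest of the others gave 274. The batches named in the labels that hold both sessions number 0, so a difference in collection, storage or library preparation cannot be told apart from the difference between sessions. A biological difference between the years or months stays open and untested.

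The 12 loci that differed between males and females were weighed in the same way. Only 2 of them overlap another locus, which argues against reads shared between overlapping loci for most of them. In the 2017 libraries alone 10 were called in the same direction. The July 2016 libraries, all female and with a session term of their own, add only to the estimate of the spread. The log2 differences between the sexes are the same without them, so that direction was fixed beforehand and tests nothing about the absence of males in 2016. Chance is an unlikely source of the count, since 1 of 100 splits, the real one, gave 12 loci or more and the highest of the others gave 1. The splits do not test single loci, and without June 2017 male 3 the count was 6. A candidate explanation is that the scaffolds holding several of the loci higher in females belong to a sex chromosome. The other 141 tested loci of these 3 scaffolds were lower in males at 61%, against 58.7% of all other loci (camera p = 0.701 with an estimated correlation), which leaves that hypothesis undecided.

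For the other comparisons chance was tested in the same way. Between September and June 2017, 1 of 100 splits, the real one, gave 5 loci or more, and the highest of the others gave 1. Between September 2017 and July 2016, 1 of 100 splits, the real one, gave 257 loci or more, and the highest of the others gave 13. For the difference of the June to September change between the sexes the real count was 0 and the highest of the others was 2. A count of 0 is reached by 100 of 100 splits by construction, so the splits say nothing about chance there.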

How the results depend on the processing

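The covariates, the length trend, the removal of short loci and of the 3 libraries with the highest share in the 10 most abundant loci, and the division of the July libraries were chosen after the data were examined. The count for September against June 2017 was the least stable. Instead of 5 loci it was 2 with a mean of at least 5 FPKM, 9 with quantile normalization, 21 with median of ratios scaling, 28 with array weights, 14 without a trend, 0 in females alone, 9 with 5 groups, 16 without the library whose title year differs from its date (July female 6, listed again among the single libraries below), 0 with relative depth as a covariate and 17 without the 3 libraries. Leaving out 1 library gave 0 to 26 loci: 0 without June 2017 female 2 or 8, September female 4 or 5 or September male 1, and 26, 23, 21, 16, 14, 13, 11, 11 and 8 without June female 6, September female 2, June male 2, July female 6, July female 2, June female 7, July female 4, September female 1 and September female 3. For July 2016 against June 2017 the count was 604 with these sessions alone, and 733 to 1011 when 1 library was left out. For September 2017 against July 2016 it was 160 in females alone, 98 with these sessions alone, and 145 to 292 when 1 library was left out, with 169, 160, 152 and 145 without September female 2, 3, 4 and 5. For sex it was 6 without the 3 libraries, and 6 (without June male 3) to 15 when 1 library was left out. The 170 loci shared by the comparisons with July were a median of 24.5 with those libraries divided. Fewer libraries entered several of these fits; otherwise the cause was not tested. No locus differed in its change between the sexes under any alternative run. Of 608 values of the named loci under alternatives, 551 kept direction and call and 57 kept direction alone. The fit without July 2016 female 6 is counted in these both as a single library left out and as the library whose title year differs. The list tests and count models planned were not run, for want of gene names and counts. Calls were fewer at low levels, which rest on fewer fragments: 4.82% of loci with a mean of 1 to 5 FPKM were called between July 2016 and June 2017, against 14.9% of those at 100 or more.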

Other observations

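The tests of mitochondrial level against depth, against collection day and for dilution by abundant loci were chosen after the level was seen to vary. Of 13167 tested loci outside the mitochondrial sequence, 1952 went with the mitochondrial level in a limma model with session and sex, 764 rising and 1188 falling with it. In females the level did not differ between sessions past the threshold (exact permutation tests, two-sided, p between 0.744 and 0.862).

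What sets the level was tested in 3 ways. After session and sex were removed, the share of the 10 most abundant loci went with 1.5% of its variance (bootstrap upper bound 26.4%, r = 0.122, permutation p = 0.533, rho = 0.0898, permutation p = 0.646, adjusted p = 0.533, r = 0.353 without the 2 farthest libraries). This argues against the share of these loci in the summed FPKM as the main source of the level. From these shares the dilution differed by up to 0.398 on the log2 scale, against a range of the level of 2.05. FPKM is divided by fragments, whose shares are unknown, so 0.398 is no upper bound on the dilution. Relative depth went with 26.5% of the variance of the level (r = 0.514, permutation p = 0.00528, rho = 0.569, permutation p = 0.00194, adjusted p = 0.00616 over 7 relations, r = 0.579 without the 2 farthest libraries), with a bootstrap upper bound of 60.7%, so depth may account for part of the level. Libraries of the same day were not closer to each other than those of other days past the threshold (one-sided permutation p = 0.21 over 15 days), which leaves the day open. Tissue composition, such as the depth of skin taken, and RNA quality were not tested and stay open.

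A short locus at positions 35881716 to 35882230 of scaffold NW_017844169.1 varied 113-fold between libraries, from 1610 FPKM in September 2017 female 4 to 182000 in June 2017 male 3, where it took 17.3% of the summed FPKM. It exceeded 20000 FPKM in 7 libraries. Its log2 level, after session and sex were removed, went against the mitochondrial level (r = -0.632, permutation p = 0.00023, rho = -0.668, permutation p = 0.00011, adjusted p = 0.000402 over 7 relations, r = -0.669 without the 2 farthest libraries). With its dilution of the other loci undone, as estimated from its share of the summed FPKM, r was -0.576. Its share of fragments, which sets the true dilution, is unknown. In a limma model with session and sex, 357 of 13191 other loci went with its level, 175 rising and 182 falling with it. The locus was chosen after its values were seen.

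The locus at positions 751341 to 772519 of scaffold NW_017843467.1 was also chosen after its values were seen. It held between 20000 and 60600 FPKM over the 28 libraries. In July 2016 it was at 53890, 56900 and 60640 FPKM in females 1, 2 and 4 and between 20610 and 26030 in the other 6 females, with no July library between. Libraries of the other sessions did lie in that gap, such as June 2017 female 7 at 35420 FPKM. September 2017 male 3, at 38770, and September 2017 female 3, at 41150, lay there as well.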
